A study of Homo sapiens with 8 samples.

How the data were processed

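MicroRNAs were measured on Exiqon miRCURY LNA arrays of the 6th generation in 4 lung cancer cell lines, H292, H358, H441 and H1437, each as a vector control and as cells with stable SNAI1 overexpression. Per the series' design text and the labels, cells were collected at equal confluency, total RNA was isolated with a column kit, and the arrays were read on a GenePix 4000B scanner with GenePix Pro 6.0. Per the file headers, the deposited scanner table holds for each array the spot flag and the median intensity in the 635 nm channel minus the local background, so the intensity is linear, already background-corrected and not normalized between arrays. The labels name the dye Hy3, but the 240 Hy3 landmark spots had medians of 7.5 to 37 in this channel, so which dye carried the sample is not settled by the sources used here. The second table holds the authors' normalized intensity for 564 probes. Per the series' design text, the authors normalized with housekeeping, spike-in and invariant endogenous microRNAs; the rule that kept these probes is not given in the sources used here.

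Each column of the authors' normalized table was set against the scanner arrays. On the log2 scale, over values above 200, r was 0.9989 to 0.9998 with its own array and at most 0.957, rounded, with another. The values were linear and not centred, with column medians of 147.0, 139.5, 156.0, 181.9, 184.0, 205.6, 173.4 and 201.4 for the H292, H358, H441 and H1437 arrays, vector before Snail in each line. They were used as an alternative.

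The scanner table holds 9360 spots with 4 spots per capture probe: 1267 probes with a human name, 351 with mouse or rat names only, 118 viral, 211 with no name, 19 small RNA controls, 10 spike-ins, 7 negative controls, and 640 empty spots. Probe names are those of the array's design. An offset of 50 was added to each intensity, values under 1 were set to 1, log2 was taken, and capture spots were quantile normalized between arrays with limma 3.58.1 in R 4.3.3. Spots of a probe were averaged on the log2 scale, so folds are on the scale of log2 of intensity plus 50 and understate changes of dim probes. Levels printed as intensity after normalization include this offset. A probe counted as detected on an array when at least 2 of its 4 spots had no flag for a spot not found, per the flags in the deposited table (unit other). Human probes detected on at least 4 of 8 arrays, 411 in all, were tested. Between 0 and 2.19% of empty spots were unflagged per array, and the 95th percentile of the empty spots was 11 to 14 intensity units. Spots at or above an intensity of 65000, taken as saturated, numbered 2 to 19 per array and were kept. The number of arrays limits the precision, and the median SD over the spots of a detected probe was 0.18 log2 units.

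Snail was compared with vector by limma's lmFit and eBayes with cell line as a block (3 residual degrees of freedom) and Benjamini-Hochberg adjustment. Lines were compared by a moderated F test with treatment as a covariate. The cell line pairs the arrays because both arrays of a pair come from the same line. The correlation of their deviations from the group means was -0.09 for H292, 0.72 for H358, 0.56 for H441 and 0.20 for H1437. Each group and line holds a single culture as far as the labels say, so p-values measure only the spread between these samples. Of the 21 lists of microRNAs fixed before the data were examined, the 16 with at least 3 tested members were tested by camera with an inter-gene correlation of 0.01, by camera with an estimated correlation and by fry. The lists are the miR-200 family, other epithelial microRNAs, the cluster of miR-183, miR-96 and miR-182, the families of miR-34 and miR-449, of let-7 and miR-98, of miR-15/16, miR-29, miR-30 and miR-181, and of miR-99, miR-100 and miR-125, the miR-17-92 cluster and paralogs, microRNAs linked to epithelial-mesenchymal transition or invasion, the clusters of miR-23, miR-27 and miR-24, miR-130 and miR-301 with miR-148 and miR-152, inflammation and hypoxia microRNAs, the 14q32 and C19MC clusters, and markers of fibroblasts, blood, other tissues and embryonic stem cells.

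The rule for named probes, also fixed before the data were examined, took up to 12 probes per direction with the largest difference among those past the adjusted threshold, filled from probes with the same sign in 4 of 4 lines and an unadjusted p under 0.05. As 0 passed, all 24 come from the fill. It added each tested miR-200 family member, 2 to 4 members with the smallest p of each other list, the 3 highest and 3 lowest probes per line, and the 8 probes with the smallest p between lines. miR-93, miR-25 and miR-106b were chosen after their values were seen. Where a named probe was not detected on 1 of the arrays of a line, its fold within that line is given as at least the detected value over the higher of its own value and the lowest signal among detected probes on the other array.

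The tests were tried on simulated data with the size and probe means of the real set. SDs were drawn from the distribution that the fit estimated, and probes were drawn independently. Changes with Snail were the same in every line, unlike the measured differences. The shares recovered therefore need not hold for the measured data. Over 20 simulations of 411 probes with 40 changed, the Snail comparison recovered 42.9% of probes changed by 1 log2 unit, 85.8% by 2 and 96.9% by 3, and 4.48% of calls were false. Camera called 10 probes lowered by 1 log2 unit in 100% of simulations and 10 unchanged probes in 5%, with probes drawn independently, unlike the measured ones. The line test called 87.25% of probes shifted by 3 log2 units in 1 line, where the lines had otherwise been given equal means.

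Alternatives covered the floor and offset, the normalization (none, median, cyclic loess, small RNA controls, spike-ins, and the authors' values), the detection filter, the spot average, mouse and rat probes, the variance model, the block, the inter-gene correlation, passenger forms, the fold threshold, and leaving out each line. The alternatives that left out a line applied the detection filter at the same share of the remaining arrays. Tested probes and list members could therefore differ between these fits. Foreground without background correction was not run, since only the subtracted column was used here. Array weights, detection above the empty spots and the estimated correlation without the H292 arrays were added after seeing the data. Gene neighbourhood was taken from the RefSeq gene table of GRCh38.p14, in which 246 of 274 tested miRBase-named probes matched a gene by name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.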

Results

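MicroRNA abundance was measured on 8 LNA capture arrays of total RNA from 4 human lung cancer cell lines. H358, H441 and H1437 were derived from lung adenocarcinomas and H292 from a mucoepidermoid lung carcinoma. Each line gave 1 array of vector control cells and 1 array of cells that stably overexpressed SNAI1, which encodes Snail, a zinc-finger repressor of CDH1 that drives epithelial-mesenchymal transition. The groups therefore held 4 vector and 4 Snail arrays, paired by cell line. Between 345 and 493 of the 1267 human probes were detected per array, 269 were detected on all 8 arrays and 642 on none. The median background-subtracted intensity of the probes detected on all arrays ran from 274 on the H358 Snail array to 748.5 on the H441 Snail array. It was higher on the Snail array than on the vector array of H441 (748.5 against 520), H1437 (703 against 506.5) and H292 (332.5 against 315), and lower in H358 (274 against 340). SNAI1 mRNA is not measured by a microRNA array, so the labels could not be checked by its level.

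The comparison of Snail with vector over the 4 lines asked which microRNAs respond to Snail overexpression. No single probe passed the adjusted threshold, so the values that follow are sizes and not called changes. The lowest Snail values relative to vector were those of miR-1274a (log2 difference -2.19 ± 0.62, SE, n = 4 lines, or 4.55-fold lower), a probe whose sequence matches a tRNA fragment, and of miR-886-3p (-1.83 ± 0.71), which derives from a vault-like RNA. miR-886-3p was at -4.01 in H292, whose Snail array did not detect it, -2.87 in H1437, -0.25 in H358 and -0.21 in H441, and at -1.11 without the H292 arrays. miR-9, a neural-enriched microRNA that targets CDH1, differed by -1.63 ± 0.32 and was detected on 4 vector arrays and 1 Snail array, so no fold is given. Its passenger form miR-9* differed by -1.29 ± 0.29. miR-19a (-1.47 ± 0.42) and miR-18a (-1.30 ± 0.31), products of the MYC-driven miR-17-92 transcript, were lower in 4 of 4 lines. The remaining probes named for lower values were miRPlus-E1013 (-1.38), miR-1264 (-1.31), miR-519d (-1.25), miR-1280 (-1.24), miR-1274b (-1.23) and miR-720 (-1.20). Each was lower in 4 of 4 lines, as the naming rule requires, but miR-720 was at only -0.0042 in H358. Without the H1437 arrays miR-19a, miRPlus-E1013, miR-519d and miR-720 were at -0.93, -0.90, -0.83 and -0.67.

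Of the 12 probes named for higher values with Snail, 10 were miRPlus probes, the manufacturer's own capture probes for sequences without a miRBase name. miRPlus-A1098 differed by 1.53 ± 0.22 (SE, n = 4 lines, 2.88-fold higher) and miRPlus-E1035 by 1.52 ± 0.21 (2.87-fold higher), each in 4 of 4 lines. miRPlus-F1159 (1.51), miRPlus-E1045 (1.42), miRPlus-E1063 (1.27), miRPlus-F1065 (1.26), miRPlus-F1170 (1.23), miRPlus-A1027 (1.13), miRPlus-A1056 (1.07) and miRPlus-D1116 (1.07) were also higher in 4 of 4 lines. The naming rule requires this sign, and miRPlus-F1170 was at only 0.096 in H292. The 2 miRBase-named probes in this set were miR-637 (1.01 ± 0.24) and miR-628-3p (0.96 ± 0.22). Among probes at an unadjusted p under 0.05, 20 of the 31 higher and 7 of the 36 lower were miRPlus probes. Fisher's exact test, two-sided, gave p = 0.000371. It was not planned, the probes it counts include the named ones, and probes are not independent replicates. Of all tested probes 137 of 411 were miRPlus probes, and their median differences were -0.40 in H292, 0.09 in H358, 0.26 in H441 and 0.32 in H1437, against -0.016, -0.16, -0.14 and -0.014 for the other human probes. The share of viral probes that were higher at an unadjusted p under 0.05 was 12.5%, against 7.54% of the human probes.

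With limma and Benjamini-Hochberg adjustment, 0 of 411 tested human probes passed an adjusted p of 0.05, and the smallest adjusted p was 0.115. At an unadjusted p under 0.05 there were 67 probes, 31 higher and 36 lower, where 20.55 would be found on average with no difference. Of the 7 other assignments of the labels within lines, the one that exchanged the labels in H358, H441 and H1437 gave 72 such probes and the others gave 0 to 13. The difference had the same sign in all 4 lines for 105 probes (42 higher, 63 lower), and chance gives 12.5% of probes, or 51.4. Probes are not independent replicates and this count was not tested, so its excess decides nothing. The median standard error of a probe's difference was 0.24 log2 units. Without the H292 arrays 15 probes passed the adjusted threshold, 13 of them higher, and 129 had an unadjusted p under 0.05, while without the H1437 arrays 0 passed and 36 had an unadjusted p under 0.05. These fits applied the detection filter to the remaining arrays. Over the 411 probes, 121 without H292 and 38 without H1437 had an unadjusted p under 0.05. The count past the adjusted threshold also moved with the scaling: 8 probes, 6 of them higher, passed with no normalization between arrays, and 2 higher ones each with median scaling, spike-in scaling and the authors' normalized values.

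**Figure D1:**
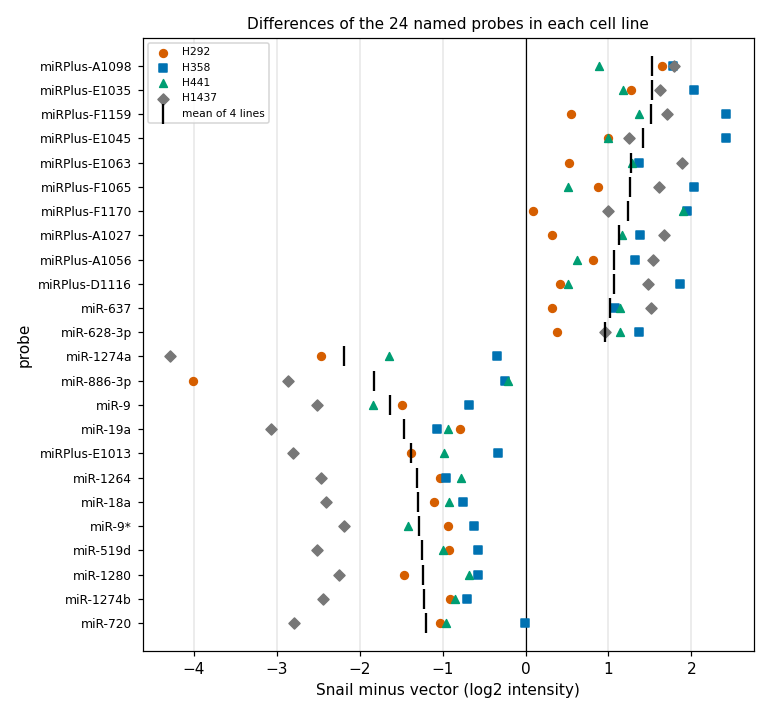
Snail minus vector difference in log2 intensity (horizontal axis) for the 24 named probes (vertical axis), with a coloured point per cell line and a black bar for the mean of the 4 lines. Each probe lies on 1 side of 0 in 4 of 4 lines, as the naming rule requires. The point farthest from 0 is miR-1274a in H1437 at -4.29.

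The miR-17-92 cluster and its paralogs, which promote proliferation and are transcribed under MYC and E2F, gave the only list that fell by limma's camera with an inter-gene correlation of 0.01 (adjusted p = 1.13e-05). The call was lost with an estimated correlation (p = 0.152, adjusted p = 0.965). The 13 tested members had mean differences below 0, with a list mean of -0.81 (SD over lines 0.59, n = 4 lines), or -0.51 without the H1437 arrays. The line medians were -0.59 in H292, -0.65 in H358, -0.56 in H441 and -1.95 in H1437. Of the members, 0 were higher and 8 lower at an unadjusted p under 0.05, 0 passed over all genes tested and 4 passed when adjusted over the list alone. Besides miR-19a and miR-18a, the smallest p were those of miR-18b (-1.19 ± 0.35) and miR-20b (-0.84 ± 0.25), lower in 4 of 4 lines. miR-93 (-0.43 ± 0.48), miR-25 (-0.15 ± 0.29) and miR-106b (-0.63 ± 0.32), which share a paralogous cluster, were higher with Snail in H292, by 1.43, 0.85 and 0.35. limma's fry, which asks whether the members move one way on balance, gave an adjusted p of 0.946. Each of the 7 other assignments of the labels within lines called 5 to 7 lists with the preset correlation, more than the 1 called with the real labels, and with estimated correlations 0 lists were called in any of the 8.

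**Figure D2:**
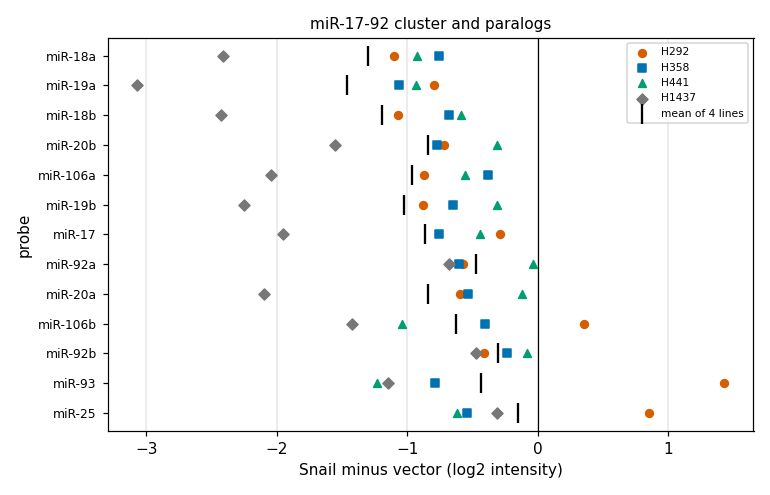
Snail minus vector difference in log2 intensity (horizontal axis) of the 13 tested miR-17-92 and paralog probes (vertical axis), with a coloured point per cell line and a black bar for the mean of 4 lines. The 13 means lie below 0, and the points above 0 are miR-93, miR-25 and miR-106b in H292, at 1.43, 0.85 and 0.35.

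The miR-200 family, which represses ZEB1 and ZEB2 and marks epithelial cells, differed in direction between lines. In H292, miR-200c was 28.9-fold higher on the Snail array, miR-200b at least 21.1-fold, miR-141 at least 18.7-fold and miR-200a at least 10.8-fold higher, since these 3 were not detected on the H292 vector array. miR-429 was detected on neither H292 array. The family medians were 4.22 log2 units in H292, -0.48 in H358, -1.86 in H441 and -2.05 in H1437. The H292 median is that of miR-141 and the H1437 median that of miR-429, which was not detected on the H1437 Snail array, so both sizes are lower bounds. Over the members detected on both arrays of a line the medians were -0.48 in H358, -2.05 in H441 and -1.68 in H1437, and in H292 miR-200c alone was so detected (4.85). Over the 4 lines the differences were 0.50 ± 1.09 for miR-200c, 0.18 ± 1.07 for miR-200b, -0.29 ± 1.15 for miR-141, -0.40 ± 0.97 for miR-200a and -0.53 ± 0.46 for miR-429 (SE, n = 4 lines). None of the 5 members passed the test over all genes or adjusted over the list alone, and the list mean was -0.11 (camera adjusted p = 0.950). Its sign turned with a floor at 1 (0.091), with an offset of 16 (0.019) and without the H358 (0.14), H441 (0.45) or H1437 arrays (0.45). The fit without H358 tested only 4 of the members, so its value also reflects the change of members. Without the H292 arrays the list mean was -1.33 and the list passed the threshold of limma's camera with the preset correlation (adjusted p = 0.0165), and was lost with an estimated correlation (adjusted p = 0.731), with miR-200c at -0.95 and miR-200b at -1.23. The 17 detected small RNA control probes had a mean log2 intensity of 11.23 on the H292 vector array, 10.39 on the H292 Snail array and 10.66 to 11.30 on the arrays of the other lines. The difference between lines itself was not tested, since each line gave 1 array per group.

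**Figure D3:**
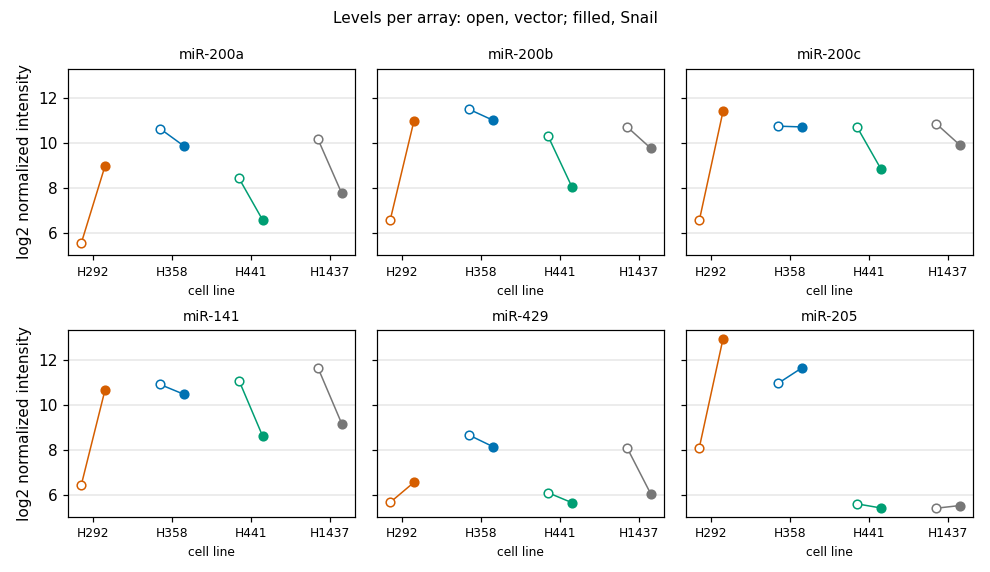
Normalized log2 intensity (vertical axis) of 5 miR-200 family probes and miR-205 in each cell line (horizontal axis), with open points for vector arrays and filled points for Snail arrays. miR-200c was at 6.56 on the H292 vector array and 11.41 on the H292 Snail array, and in H441 its Snail minus vector difference was -1.85.

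The other epithelial microRNAs gave 0 of 5 members at an unadjusted p under 0.05 (list mean 0.06, list median -0.07, camera direction down). The list mean was -0.16 with a floor at 1, -0.14 to -0.027 with median, cyclic loess, small RNA control or spike-in scaling, and -0.54 to 0.37 when a line was left out. The fits without H292, H358, H441 and H1437 tested 3, 3, 5 and 4 members, so this range also reflects the change of members. miR-205, which like the miR-200 family targets ZEB1 and ZEB2, was 28.6-fold higher on the Snail array of H292 and differed by 1.37 ± 0.86 over the lines, though it was not detected in H441 and H1437. miR-203 differed by -0.92 ± 0.69, or by -0.023 without the H1437 arrays, of which the Snail array did not detect it. Among microRNAs linked to epithelial-mesenchymal transition or invasion, 0 of 7 were higher and 1, miR-9, was lower at an unadjusted p under 0.05, and miR-9 passed when adjusted over the list alone (adjusted p = 0.0175, limma with Benjamini-Hochberg adjustment). miR-221 differed by 0.94 ± 0.43. The list median was -0.03 and its camera direction was up, and its mean of 0.00082 was -0.32 with a floor at 1, -0.18 with passenger forms, -0.12 with an offset of 16, and -0.25 to 0.22 when a line was left out. The family of miR-99, miR-100 and miR-125 had 1 of 5 members higher, miR-125a-5p (0.87 ± 0.31), and miR-99b differed by 0.58 ± 0.30. The mean of this list was 0.45, or 0.15 without the H292 arrays and 0.69 without those of H441, where only 4 members were tested. The clusters of miR-23, miR-27 and miR-24 had a mean of 0.64, or -0.071 without the H292 arrays, with 0 of 5 members at an unadjusted p under 0.05, miR-23b at 0.75 ± 0.58 and miR-27b at 0.50 ± 0.41. In the 14q32 imprinted cluster 1 of 10 members, miR-487b (-1.10 ± 0.38, and -0.65 without the H1437 arrays), was lower at an unadjusted p under 0.05, and miR-299-3p differed by -0.47 ± 0.21. The 14q32 list mean was -0.17, or -0.11 without the H292 arrays and 0.0042 with no normalization. In the C19MC cluster 1 of 7, miR-519d, was lower at an unadjusted p under 0.05 (list mean -0.05, list median 0.14, camera direction up), and the mean was 0.090, 0.031 and 0.022 with no normalization, spike-in scaling and the authors' values, and -0.11 to 0.043 when a line was left out.

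No member passed an unadjusted p of 0.05 in the lists that follow. The let-7/miR-98 family had a mean of 0.11 over 9 members, with let-7b at -0.28 ± 0.18 and let-7e at 0.35 ± 0.24. The miR-15/16 family had a mean of 0.12 over 5 members, with miR-195 at 0.43 ± 0.25 and miR-15a at 0.28 ± 0.43. The miR-29 family had a mean of -0.42 over 3 members, or -0.70 without the H292 arrays and -0.25 without those of H441, with miR-29c at -0.45 ± 0.24 and miR-29b at -0.67 ± 0.35. The miR-30 family had a mean of 0.16 over 5 members, with miR-30b at 0.28 ± 0.38 and miR-30c at 0.22 ± 0.35. The cluster of miR-183, miR-96 and miR-182 had a mean of 0.02 over 3 members, a median of -0.05 and a camera direction of down, with miR-183 at -0.26 ± 0.24 and miR-182 at 0.37 ± 0.52. The list of miR-130, miR-301, miR-148 and miR-152 had a mean of -0.14 over 4 members, or 0.20 without the H1437 arrays and -0.59 without those of H292, with miR-148b at -0.54 ± 0.36 and miR-130a at 0.66 ± 0.47. Inflammation and hypoxia microRNAs had a mean of -0.04 over 3 members, a median of 0.01 and a camera direction of down, with miR-155 at -0.22 ± 0.32 and miR-146b-3p at 0.08 ± 0.22. The means of the miR-183 cluster were -0.046 to -0.011 with median, cyclic loess or small RNA control scaling, and those of the inflammation and hypoxia microRNAs 0.032 to 0.12 with no normalization, spike-in scaling or the authors' values. When a line was left out these means were -0.47 to 0.23 and -0.21 to 0.10. Without the H292 arrays the means of the let-7, miR-15/16 and miR-30 families were -0.057, -0.22 and -0.34. Leaving out 1 line moved each of the 15 uncalled list means by over 1.5 times or turned its sign, and did so for 34 of 38 probes tried in this way outside the 24 named ones. Several of these means lay near 0, such as 0.02 for the miR-183 cluster, where small moves exceed this ratio. List members could also differ between the fits, so these counts do not measure stability. The called miR-17-92 mean also moved by over 1.5 times, from -0.81 to -0.51 without the H1437 arrays. The camera adjusted p of the 15 tested lists other than miR-17-92 ran from 0.398 to 0.950.

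Markers of other cell types were sparse. Of the fibroblast and mesenchymal markers 3 of 8 probes were tested (list mean -0.02, 0.15 and 0.093 with no normalization and spike-in scaling, and -0.13 to 0.065 when a line was left out), with miR-140-3p at -0.14 ± 0.19 and miR-214 at 0.12 ± 0.20. Of the blood cell markers only miR-150 was tested (0.19 ± 0.19), and of the muscle, liver, neural and endothelial markers miR-126 (-0.58 ± 0.34) and miR-206 (-0.32 ± 0.28). The embryonic stem cell clusters had 0 of 9 probes tested. The family of miR-34 and miR-449, with miR-34a (-0.40 ± 0.63) and miR-34b (-0.13 ± 0.16, and 0.097 with no normalization), and the miR-181 family, with miR-181a (0.56 ± 0.50) and miR-181b (0.50 ± 0.53), had 2 tested members each and no list test.

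The differences within each line have no replicate and no test. In H292, 100 of 431 probes detected on at least 1 of the line's arrays differed over 2-fold, 60 higher and 40 lower with Snail. The highest values relative to vector were those of miR-200c (28.9-fold), miR-205 (28.6-fold) and miR-200b, and the lowest values were those of miRPlus-E1088 (16.3-fold lower), miR-886-3p (at least 16.1-fold lower) and miRPlus-A1087 (at least 10.9-fold lower). In H1437, 101 of 544 probes differed over 2-fold, 46 higher and 55 lower. miRPlus-E1063 (3.72-fold), miR-221 (3.58-fold) and miRPlus-A1098 (3.45-fold) were higher, and miR-1274a (19.5-fold), miR-203 (at least 12.1-fold) and miR-19a (8.41-fold) were lower. In H441, 40 of 514 probes differed, 22 higher and 18 lower, with miRPlus-F1170 (3.73-fold), miRPlus-E1077 (3.13-fold) and miR-513b (2.74-fold) higher, and miR-141 (5.58-fold), miR-200b (4.75-fold) and miR-200a (3.63-fold) lower. In H358, 19 of 394 probes differed, 17 higher and 2 lower. miRPlus-D1036 (5.50-fold), miRPlus-E1045 (5.34-fold) and miRPlus-F1159 (5.33-fold) were higher. miR-7 (2.44-fold) and miR-19a (2.09-fold) were lower, followed by miR-1264 (1.94-fold). On the H358 Snail array the SD over spots was 0.88 log2 units for miR-7 and 0.75 for miR-19a, against an array median of 0.22.

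Across the 411 tested probes, the differences of H358, H441 and H1437 ran alike and those of H292 did not. Pearson's r was 0.71 between H441 and H1437, 0.61 between H358 and H441 and 0.55 between H358 and H1437. It was -0.02, -0.22 and 0.09 between H292 and H358, H441 and H1437. These correlations are across probes, which are not independent replicates. Small RNA control probes, which measure small nuclear, small nucleolar and ribosomal RNAs, had median differences of -0.80 in H292, 0.04 in H358, 0.23 in H441 and 0.44 in H1437.

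Levels between cell lines are given as geometric mean normalized intensity, which includes the offset of 50. Between cell lines, averaged over treatments, the probes with the smallest p were miR-193a-3p, miR-193b, miR-31, miR-365, miR-424, miRPlus-F1027, miR-377 and miRPlus-A1098. The geometric mean intensity of miR-193b was 1016 in H1437, 443 in H292, 383 in H358 and 112 in H441, and that of miR-365, encoded beside it, was 604, 366, 263 and 89.9 in the same order. miR-193a-3p was at 440 in H358, 164 in H1437 and 143 in H292, and was not detected in H441. miR-31 was at 205 in H292 and 168 in H358, and was not detected in H1437 and H441. miR-424 was at 610 in H358 and 185 in H1437, and was not detected on the H441 Snail array. miR-377 was at 280 in H1437, 211 in H358 and 192 in H441, miRPlus-F1027 was at 224, 175 and 166 in these lines, and neither was detected in H292. miRPlus-A1098 was at 2006 in H441 and 431 in H358. In limma's moderated F test with Benjamini-Hochberg adjustment 0 of 411 probes passed the adjusted threshold (smallest adjusted p 0.0764), and 74 had an unadjusted p under 0.05. Without the H292 arrays 18 probes passed and 134 had an unadjusted p under 0.05, against 40 without H358, 43 without H441 and 83 without H1437. With no normalization between arrays 60 probes passed, with a floor at 1 there were 11, with spike-in scaling 9, and with an offset of 16 or a variance trend 6.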

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

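The tests of H292 against a uniform loss, of brightness, of the miR-18 and miR-19 members, of the count of probes over relabelled arrays and of the lists called there with estimated correlations were chosen after their results were seen. In 94 groups of 4 arrays, 10 held an array whose gap to its nearest neighbour exceeded the 95% limit relative to the group's range, where chance gives about 1 in 20, or 4.7. H292 stood apart on the vector arrays for miR-200c (ratio 0.963; 6.56 in H292 against 10.71 to 10.87 log2 units), miR-141 (0.859; 6.43, not detected, against 10.91 to 11.65), the mean of the miR-183, miR-96 and miR-182 cluster (0.832) and the mean of the fibroblast and mesenchymal markers (0.933), and on the Snail arrays the mean of the 14q32 cluster (0.8291). H358 stood apart on the Snail arrays for miR-9 (0.864, with 8.80 against 5.62 to 6.05) and miR-9* (0.866). The Snail arrays of H292, H441 and H1437 did not detect miR-9, and those of H292 and H1437 did not detect miR-9*. The narrow range of the other arrays is thus partly or wholly one of undetected signal. H1437 stood apart on the Snail arrays for miR-886-3p (0.914, with 9.43 against 6.41 to 6.67), which the H292 Snail array did not detect. H441 stood apart for miR-628-3p on the Snail arrays (0.851) and for miR-1280 on the vector arrays (0.843).

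The miR-200 family median differed by 6.27 log2 units between H292 (4.22) and H1437 (-2.05), an opposite direction that was not tested, with 1 array per line and group. These are values of miR-141 and miR-429, each not detected on 1 array of the line, so both sizes are lower bounds. Outside the comparisons, 71 of 351 mouse or rat probes, 10 of 118 viral probes and 67 of 211 unnamed probes were detected on all 8 arrays, against 0 of 7 negative control probes. The brightest viral probe was ebv-miR-BART2-3p, with a mean intensity of 968.

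H292 moved apart from the other lines. A uniform loss of mature microRNAs from its vector array would by itself shift lists alike. The medians of let-7 (0.69), miR-17-92 (-0.59) and miR-200 (4.22, a lower bound) spanned 4.82 log2 units. Such a loss alone does not give this span. Whether a loss took part cannot be decided, since quantile normalization removes a shift common to all probes of an array. The small RNA control probes had a median difference of -0.80 in H292. Exchanged labels of the 2 H292 arrays could not be excluded. Over the 411 probes, 121 had an unadjusted p under 0.05 without H292. Of these, 49.6% went the opposite way in H292 (exact binomial 95% interval 40.4% to 58.8%). The shares were 16.7%, 4.17% and 2.63% when H358, H441 or H1437 was left out and set against the rest in the same manner. With the H292 labels exchanged, 72 probes had an unadjusted p under 0.05, against 67 as labelled. A response to Snail that depends on the line stays open and untested.

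Probes higher with Snail at an unadjusted p under 0.05 may come from non-specific signal. The viral share was 12.5% (3 of 24; exact binomial 95% interval 2.66% to 32.4%) and the human share 7.54%, as that explanation needs, although Fisher's exact test, two-sided, gave p = 0.421 and 24 probes decide little. A trend with brightness could not be excluded: the largest absolute correlation of a line's differences with mean intensity over the 411 probes was 0.10, but quantile normalization holds such correlations near 0 whatever the cause. An effect of Snail stays open. Of the 8 assignments of labels that part every line, 2 gave at least 67 probes (highest other 72), and 8 assignments are too few for a share under 0.05.

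The miR-17-92 list fell with the preset correlation and was lost with an estimated one (adjusted p = 0.965; 0.618 to 0.9999 over the 4 fits that leave out a line). With the preset correlation the highest camera p over these fits was 4.48e-06 (list mean -0.51 without H1437). That correlation called lists under every assignment of labels, so a small p cannot show how much 1 line contributed. The median was below 0 in each line, from -0.56 in H441 to -1.95 in H1437. The miR-18 and miR-19 probes had a mean of line medians of -1.22 (SD over lines 0.81). The fall was therefore not confined to near-identical miR-17 sequences. These probes are themselves similar pairs, miR-18a with miR-18b and miR-19a with miR-19b, so similar probes counted as several are not excluded. All 8 assignments of labels called at least 1 list, and the other 7 called 5 to 7 (highest other 7), which points to a structure of the samples; with estimated correlations each assignment called 0, so the excess is not told apart from an effect of the preset correlation. The 8 assignments are too few for a share under 0.05. The correlation within the list was estimated at 0.58 over the 4 lines, so its 13 members are not independent. This estimate depended on the H1437 arrays: it was 0.50, 0.63 and 0.76 without H292, H358 and H441, and 0.0080 without H1437. In the fit without H1437, camera with the estimated correlation gave p = 0.0386 (adjusted p = 0.618). An effect of Snail stays open.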

How the results depend on the processing

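Array weights, detection above the empty spots and the estimated correlation without H292 were chosen after seeing the data; the other alternatives were planned, and the planned one without background correction was not run. The 24 named probes kept their sign in all 451 values under alternatives, of which 21 passed the adjusted threshold. They were chosen for 1 sign in 4 of 4 lines, so leaving out a line could not turn it, and these values are no measure of robustness. The miR-17-92 list passed in 22 alternatives with a preset correlation (mean -1.0 to -0.51, the latter without H1437, adjusted p 1.44e-08 to 0.000143) and was lost with an estimated correlation (adjusted p = 0.965), where 0 lists passed. Without H292 and with an estimated correlation 0 lists passed (miR-200 family adjusted p = 0.731). Leaving out each line gave 1 to 2 lists. Without the replicate block, 0 probes passed, 46 had an unadjusted p under 0.05 and the list had adjusted p = 8.35e-05, so the pairing changed no call. The median of all differences was 0.19 with no normalization, 0.13 with spike-in scaling and 0.13 with the authors' values, so those counts of higher probes are relative to a shift. Signal over background limits dim probes, whose values move with the offset. For the changes below the cause was not tested, except that leaving out a line removes arrays.

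The count of 0 probes became 8 with no normalization (6 higher), 2 with median scaling, 2 with spike-in scaling, 2 with the authors' values and 29 with array weights (22 higher). Leaving out each line gave 0 to 15, the latter without H292. The 74 probes at an unadjusted p under 0.05 between lines became 134, 40, 43 and 83 without H292, H358, H441 and H1437. The 67 probes at an unadjusted p under 0.05 became 139 with no filter, 108 with array weights and 36 to 129 without each line. Between lines, 0 became 11 with a floor at 1, 6 with an offset of 16, 60 with no normalization, 2 with cyclic loess, 9 with spike-in scaling, 1 with no filter, 2 with mouse and rat probes, 6 with a variance trend, 33 with array weights and 0 to 18 without each line. Counts over 2-fold in H292, H358, H441 and H1437 became 178, 50, 122 and 221 with a floor at 1. At 1.5-fold they were 194, 66, 119 and 208, and at 3-fold 47, 8, 10 and 46. H358, H441 and H1437 gave 34, 78 and 164 with an offset of 16. H441 and H1437 gave 96 and 160 with no normalization and 26 and 64 with detection on all 8 arrays. H441 gave 74 with small RNA control scaling, and H1437 gave 159 with spike-in scaling.

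Values that changed sign passed the threshold in 0 of 68 cases. With a floor at 1 and no offset, the differences were: miR-200a 0.41, the miR-200 family mean 0.091, the other epithelial miRNAs mean -0.16, the miRNAs linked to EMT or invasion mean -0.32, the inflammation and hypoxia miRNAs mean 0.036. With an offset of 16, the differences were: the miR-200 family mean 0.019, the other epithelial miRNAs mean -0.071, the miRNAs linked to EMT or invasion mean -0.12. With no normalization, the differences were: miR-34b 0.097, miR-140-3p 0.069, the inflammation and hypoxia miRNAs mean 0.12, the 14q32 imprinted cluster mean 0.0042, the C19MC cluster mean 0.090, the fibroblast and mesenchymal markers mean 0.15. With median scaling, the differences were: the other epithelial miRNAs mean -0.13, the miR-183 cluster mean -0.012. With cyclic loess, the differences were: the other epithelial miRNAs mean -0.14, the miR-183 cluster mean -0.046, the miRNAs linked to EMT or invasion mean -0.019. With small RNA control scaling, the differences were: the other epithelial miRNAs mean -0.13, the miR-183 cluster mean -0.011. With spike-in scaling, the differences were: miR-34b 0.038, miR-140-3p 0.0095, the other epithelial miRNAs mean -0.027, the inflammation and hypoxia miRNAs mean 0.063, the C19MC cluster mean 0.031, the fibroblast and mesenchymal markers mean 0.093. With the authors' values, the differences were: the inflammation and hypoxia miRNAs mean 0.032, the C19MC cluster mean 0.022. With no filter, the differences were: the other epithelial miRNAs mean -0.052, the miRNAs linked to EMT or invasion mean -0.0089, the inflammation and hypoxia miRNAs mean 0.075, the fibroblast and mesenchymal markers mean 0.015. With the median of spots, the differences were: the miRNAs linked to EMT or invasion mean -0.0027. With passenger forms, the differences were: the miRNAs linked to EMT or invasion mean -0.18.

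Leaving out a line gave ranges that crossed 0 for miR-200c -0.95 to 1.29, miR-200b -1.23 to 0.99, miR-182 -0.30 to 0.69, miR-15a -0.27 to 0.54, miR-30b -0.18 to 0.49, miR-30c -0.21 to 0.40, miR-23b -0.0018 to 1.12. Ranges across 0 were also found for miR-27b -0.00051 to 0.79, miR-181a -0.093 to 0.80, miR-181b -0.20 to 0.75, miR-155 -0.40 to 0.14, the other epithelial miRNAs mean -0.54 to 0.37, the miR-183 cluster mean -0.47 to 0.23, the let-7/miR-98 family mean -0.057 to 0.30. The same held for the miR-15/16 family mean -0.22 to 0.31, the miR-30 family mean -0.34 to 0.37, the miRNAs linked to EMT or invasion mean -0.25 to 0.22, the miR-23 clusters mean -0.071 to 1.01, the inflammation and hypoxia miRNAs mean -0.21 to 0.10, the C19MC cluster mean -0.11 to 0.043, the miR-200 family mean -1.33 to 0.45. It held too for the fibroblast and mesenchymal markers mean -0.13 to 0.065, miR-200a -1.68 to 0.27, miR-141 -1.80 to 0.44, miR-34a -1.22 to 0.069, miR-146b-3p -0.11 to 0.20, the miR-130, miR-301, miR-148 and miR-152 list mean -0.59 to 0.20. The tested members of some lists differed between these fits, so part of a list's range can come from the change of members.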

Other observations

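The test of the tRNA-derived probes and the neighbour check without the miR-17-92 and C19MC probes were chosen after the results were seen, as were the probes named in this part; normalized intensities include the offset of 50. In H292, miR-24 was at an intensity of 570 on the vector array and 11127 on the Snail array, a 19.5-fold difference, while in H358, H441 and H1437 its Snail minus vector differences were -0.21, -0.18 and -0.12. The oncogenic miR-21 was 4.88-fold higher with Snail in H292 and differed by -1.75 in H441, and its passenger form miR-21*, not detected on the H292 vector array, was also higher in H292 and differed by -0.86 in H441. miR-221 and miR-222, made from the same transcript, differed by 1.95 and 1.87 in H292, by 1.84 and 1.14 in H1437, by -0.06 and 0.22 in H358 and by 0.05 and -0.25 in H441. The vault-like RNA probes miR-886-3p and miR-886-5p were bright on the vector arrays of H1437 (5021 and 1744) and H292 (1372 and 356) and dimmer on their Snail arrays, at 689 and 362 in H1437 and not detected in H292. miR-1246 and miR-1290 differed by -0.99 ± 0.35 and -1.11 ± 0.25 over the 4 lines, with adjusted p of 0.257 and 0.155 (limma with Benjamini-Hochberg adjustment).

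Without the H292 arrays and over the 411 probes, 15 probes passed, 13 higher and 2 lower, of which 11 had the same sign in H292 and 4 the opposite one. Of the miRBase-named ones not given before, miR-7 differed by -1.33 ± 0.14, miR-93 by -1.05 ± 0.16 and miR-513a-5p by 1.37 ± 0.14, with adjusted p of 0.0283, 0.0411 and 0.0283 (limma with Benjamini-Hochberg adjustment). In H292 their differences were -0.16, 1.43 and -0.55.

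A hypothesis was that microRNAs encoded within 10 kb of each other move alike because they share a transcript. The median distance between the 4-line profiles of 109 neighbour pairs with different name numbers was 1.26 log2 units. For random pairs it was 1.75 (one-sided permutation p = 0.0001, the smallest that 10000 random sets can give). The direction is the one the hypothesis needs. The 109 pairs reuse 77 probes, while random pairs were drawn independently, so the p-value overstates the evidence. Without the miR-17-92 and C19MC probes, many of which resemble each other in sequence, 56 pairs had a median of 1.44 against 1.71. The one-sided permutation p was 0.0504, with the same limit, so similar sequences may carry part of the pattern.

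Of 5 probes named for tRNA-derived sequences, miR-1274a, miR-1274b, miR-720 and miR-1280 had mean differences of -1.20 to -2.19 and miR-1308 of 0.14. Camera gave p = 0.00357 with the preset correlation and p = 0.182 with an estimated one, but the probes were picked because they were low with Snail, so the test decides nothing about tRNA fragments.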
